A study of Mus musculus with 4 samples.

How the data were processed

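The data were gene counts of single cells from mouse colon, 2 libraries of control mice and 2 of mice given CCl4 for 6 weeks from 6 weeks of age. Per the labels, colon tissue was dissociated enzymatically, cells were caught in droplets with barcoded beads, and polyadenylated RNA was sequenced. The labels do not say how many animals went into a library, whether the libraries of a group share animals, or what the numbers 1 and 2 of the libraries mark. The deposited matrices held raw counts per gene and cell barcode, written by PISA v0.12b per the file headers. The submitters' processing notes gave the genome build GRCm38. The aligner is not given in the sources used here. The counts were whole numbers, and the lowest total of a barcode was 1001 or 1002 in each library, so a floor of 1000 counts had been applied before deposition. The files listed 29897 genes in any library and 26185 in all 4. Of the gene symbols, 98.4% were in the GENCODE M21 annotation, which gave the positions.

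The libraries held 10021, 10038, 13986 and 12464 barcodes, in the order control 1, control 2, CCl4 1 and CCl4 2. Cells with at least 200 genes and at most 25% mitochondrial counts were kept, which left 8620, 8771, 11045 and 10416. Scrublet in scanpy 1.11.5 scored doublets in each library, and the 6% of cells with the highest scores were removed in every library (544, 542, 668 and 629 cells). A first version used the automatic threshold, which called 139, 168, 187 and 0 cells, and took the 6% only in the library without calls. It was replaced after the data were seen, since it treated the libraries unequally, and was kept as an alternative. The number of cells used was 8076, 8229, 10377 and 9787, and the median mitochondrial share in them was 4.84%, 4.54%, 7.51% and 6.84%. Of 38852 filtered cells, 0 had the same profile as a cell of another library.

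Counts were scaled to a common total per cell and log transformed, and 2000 variable genes were taken, leaving out rearranged antigen receptor segments. A shared neighbour graph of 15 neighbours on 30 principal components was clustered with leidenalg 0.10.2 at resolution 1.0 (igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15). No batch correction was made. Clusters were named from 24 marker sets. For each set, the mean log2 ratio of a cluster over all other cells was taken after adding 10 CPM. A name needed at least 3 markers raised by a log2 ratio of 1 and found in at least 10% of the cluster's cells, a lead of 0.5 over the next set, and no larger number of another set's markers among the 10 leading genes. Clusters that failed were left unnamed: 6 clusters with 6351 cells. The details of this rule, the exclusion of receptor segments and the change of the detection share from 25% to 10% were chosen after the data were seen. At 25% only the natural killer and innate lymphoid cluster lost its name. A smooth muscle cluster with a fibroblast score of at least 1 was kept in its class, and an alternative left it out.

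Raw counts were summed over the cells of a class in each library, and 8 classes with at least 50 cells in every library and the most cells were fitted. The sums held between 1647577 and 12330800 counts. Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the low-count filter filterByExpr, treatment as the only factor, and Benjamini-Hochberg adjustment within a class at 0.05. The biological coefficient of variation lay between 0.0874 and 0.154. Within a group, the variance of counts between libraries exceeded counting noise by a mean factor of 2.14 to 4.85. Cells per class were tested with the same edgeR test with the total cells as library size, for classes with at least 20 cells. Of the 33 gene lists written down beforehand, those with at least 5 members past the filter were tested with camera in limma 3.58.1 on voom values, at the preset correlation of 0.01, with adjustment over all pairs of a list and a class. The lists cover immune and stress responses, epithelial functions, metabolism, matrix, proliferation and transcripts that can leak. Differences between classes in a gene's change were tested with an interaction term in edgeR. All tests between groups were two-sided. Plasma cells, glia, natural killer and innate lymphoid cells and lymphatic endothelial cells also met the minimum of 50 cells. They were fitted after the data had been seen, outside the 8 planned classes.

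Genes were named by a rule fixed beforehand. Among called genes with a mean of at least 50 CPM in either group, the 8 with the largest rise and the 8 with the largest fall were named in the 3 largest classes, and 4 and 4 in the others. Genes of uncertain annotation, ribosomal and mitochondrial genes and variable receptor segments were left out of this part. The 3 members with the smallest p were added from each list past the threshold in a class. The text gives a selection of these. Genes outside the rule are said to be so where they appear.

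Alternatives planned beforehand were DESeq2 1.42.0, relative log expression factors, no low-count filter, the library number as a block, each library left out in turn, doublets kept, stricter cells with at least 500 genes and at most 10% mitochondrial counts, and resolution 2.0. For shares, TMM factors and separate epithelial and non-epithelial totals were planned, and for lists an estimated correlation and the rotation test fry. With a library left out, its group had 1 sample, which the model takes to vary like the other group. Alternatives added after the data were seen were the first doublet rule, the first naming rule, a clustering without called genes, smooth muscle without the mixed cluster, and free RNA subtracted. For the last, the share of free RNA was read from Igha outside plasma cells (medians of 1.28%, 1.44%, 1.60% and 1.77%), and that share of the whole library's profile was taken off. It removed too little epithelial RNA, as the closing part shows.

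The pipeline was tested on simulated data made from the summed counts, with 200 genes changed. Of 100 genes changed 2-fold, it recovered 73 in fibroblasts, 62 in undivided epithelial cells, 76 in colonocytes, 48 in T cells, 50 in endothelial cells, 43 in macrophages, 73 in goblet cells and 47 in smooth muscle. Of 100 changed 4-fold it recovered between 79 and 95. Between 3 and 16 unchanged genes were called per class, and 0 unchanged lists in every class. The simulated genes varied independently of one another, so the simulation cannot show how often a list of correlated genes is called wrongly. Figures were drawn with matplotlib 3.10.9.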

Results

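Droplet single-cell RNA sequencing of the colon was compared between control mice and mice given carbon tetrachloride (CCl4), a liver toxin used to bring on liver cirrhosis in rodents. Per the labels, CCl4 treatment began at 6 weeks of age and lasted 6 weeks. No age or duration was recorded for the control libraries. Each group had 2 libraries. The comparison addresses which cell types and transcripts of the colon differ in mice given CCl4. The data hold no measure of the liver, so cirrhosis in these mice is not shown here. The control libraries held 55834301 and 58667918 counts in 10021 and 10038 cell barcodes. The CCl4 libraries held 92383719 and 74643979 counts in 13986 and 12464 barcodes. Each deposited barcode held over 1000 counts, with a median of 3703 and 3926 in the control libraries and 4341 and 3927 in the CCl4 libraries. The median mitochondrial share of counts was 6.05% and 5.65% in the control libraries and 10.7% and 9.08% in the CCl4 libraries. At a limit of 25% mitochondrial counts, 13.7% and 12.4% of control barcodes and 20.9% and 16.2% of CCl4 barcodes were removed. After this limit, a minimum of 200 genes and the removal of the 6% of cells with the highest doublet scores, 8076 and 8229 control cells and 10377 and 9787 CCl4 cells remained.

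Cells fell into 31 clusters, and all but 6 of these took the name of 1 of 16 classes from markers listed beforehand. The class names are short for "fibroblast-like", "goblet-like" and so on. Cells with the shared epithelial markers but without a clear lead for a single epithelial type are called undivided epithelial. The 6 unnamed clusters held 12.02% and 16.9% of control cells and 17.9% and 21.8% of CCl4 cells. The tests, classes, gene lists and rule for naming genes were set before the data were examined, except where stated. Levels are CPM, the summed counts of a class scaled by edgeR to a common total per library, given as mean ± SD over n = 2 libraries. Changes are log2 ratios of CCl4 over control from edgeR with their standard error (SE). The p-values measure only the spread between these libraries, which may be technical, since the labels do not say that the libraries came from separate animals. An exact permutation of 2 against 2 libraries cannot give a two-sided p under 2 in 6, so the calls rest on edgeR and limma models that pool the spread over genes or classes.

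The colon of CCl4 mice yielded larger shares of goblet cells, which secrete the mucus layer, and of undivided epithelial cells. It yielded smaller shares of plasma cells, which make secretory antibody, and of T cells and fibroblasts. Goblet cells rose from 3.12% ± 0.0501 to 7.83% ± 0.314 of cells (mean ± SD, n = 2; log2 ratio 1.33, SE 0.107, edgeR adjusted p = 1.445e-12). Undivided epithelial cells rose from 5.39% ± 0.583 to 11.6% ± 0.791 (1.10, SE 0.0961, adjusted p = 3.985e-12). Plasma cells fell from 6.66% ± 0.314 to 2.76% ± 0.222 (-1.27, SE 0.109, adjusted p = 3.985e-12). T cells fell from 9.87% ± 0.140 to 6.03% ± 0.753 (-0.71, adjusted p = 5.585e-08), and fibroblasts from 25.8% ± 0.0038 to 18.3% ± 0.598 (-0.50, adjusted p = 2.648e-06). B cells were a small class that rose from 0.480% ± 0.197 to 1.43% ± 0.0243 (1.58, adjusted p = 1.612e-08). In these 6 classes both CCl4 libraries lay on the same side of both control libraries.

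Smaller changes were called for smooth muscle cells (-0.38, edgeR adjusted p = 0.001988), macrophages and monocytes (-0.33, adjusted p = 0.003322), colonocytes (0.27, adjusted p = 0.01207) and endothelial cells (-0.25, adjusted p = 0.02136). Erythroid cells, 1 and 0 in the control and 24 and 12 in the CCl4 libraries, made up 0.0062% ± 0.0088 of control cells and 0.177% ± 0.0768 of CCl4 cells (adjusted p = 1.23e-05). Shares of enteroendocrine cells, lymphatic endothelial cells, glia, natural killer and innate lymphoid cells and interstitial cells of Cajal were not past the threshold (adjusted p = 0.06216, 0.1433, 0.1505, 0.2971 and 0.6349). In all, 11 of 16 classes were past it, and between 5 and 12 when each library was left out in turn. Shares depend on one another. Within the epithelial cells alone the colonocyte change turned to -0.55. Within the non-epithelial cells alone the changes of endothelial cells, macrophages and smooth muscle cells turned to 0.19, 0.10 and 0.05, and that of fibroblasts was no longer past the threshold (-0.065). Goblet (0.50), undivided epithelial (0.28), plasma (-0.83), T (-0.28) and B cells (2.01) stayed past it in those totals.

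The shares rest on barcodes above the floor of 1000 counts, on the mitochondrial limit, which removed more CCl4 than control barcodes, and on libraries whose median depth differed as given above. A clustering without the 1007 genes called between groups in any class gave 1.31 for goblet, -1.29 for plasma, -0.71 for T, 1.55 for B, -0.50 for fibroblast, -0.33 for macrophage, -0.37 for smooth muscle and -0.25 for endothelial cells, all still past the threshold. Colonocytes were not past it there (0.17). Undivided epithelial and erythroid cells got no class of their own in that clustering. The undivided epithelial call was not past the threshold without CCl4 library 1 (1.03), and the B cell call without CCl4 library 1 (1.60) or 2 (1.56). The same held for macrophages without CCl4 library 1 (-0.36) or 2 (-0.30), for smooth muscle without CCl4 library 2 (-0.33), and for erythroid cells without CCl4 library 2 (4.95; no value without CCl4 library 1). Colonocytes were not past it without control library 2 (0.17), CCl4 library 1 (0.36) or CCl4 library 2 (0.18). Endothelial cells were not past it without control library 1 (-0.21), CCl4 library 1 (-0.28) or CCl4 library 2 (-0.21).

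**Figure D1:**
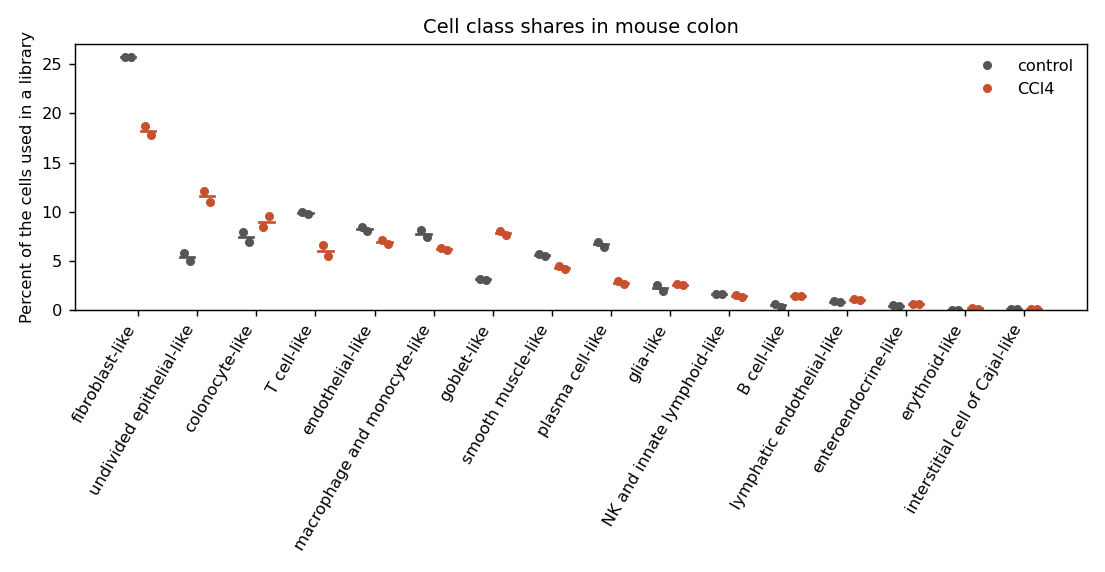
Share of the retained cells in each named class, in percent, with bars for the mean of 2 libraries and dots for the libraries. Goblet cells averaged 3.12% in control and 7.83% in CCl4 libraries, and plasma cells 6.66% and 2.76%.

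Within the classes, 1436 genes were called at an adjusted p under 0.05 in the 8 largest testable classes, 862 higher and 574 lower in CCl4. The sum runs over classes, so a gene called in several classes counts several times. Undivided epithelial cells held 375 calls (172 higher, 13030 genes tested), fibroblasts 266 (190 higher, 15280 tested) and smooth muscle cells 260 (181 higher, 10642 tested). Colonocytes held 159 calls (62 higher, 13104 tested), macrophages and monocytes 140 (102 higher, 10984 tested) and goblet cells 113 (77 higher, 12350 tested). Endothelial cells held 80 (54 higher, 12026 tested) and T cells 43 (24 higher, 10715 tested). The sum was 3016 without control library 1 and 2447 without control library 2, and 1385 and 1004 without CCl4 library 1 and 2. Without the low-count filter edgeR called 0 of 24993 genes in colonocytes, with 1610 at an unadjusted p under 0.05. DESeq2 called 122 there, with the filter. In spiked simulations on these counts, between 43 and 76 of 100 genes changed 2-fold were recovered per class, so a gene that was not called is not shown to be unchanged.

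Epithelial cells of CCl4 mice carried lower levels of antigen presentation and interferon-response transcripts. In colonocytes, the absorptive cells of the colon surface, Psmb8 fell from 120 ± 0.619 to 29.7 ± 0.0450 CPM (log2 ratio -2.01, SE 0.0960, edgeR adjusted p = 1.567e-08). Psmb8 encodes a subunit of the immunoproteasome, which cuts proteins into peptides for MHC class I, and lies on chromosome 17 at 34197721 to 34201454 of GRCm38. Its neighbour Psmb9, at 34181987 to 34187764, encodes another such subunit and fell from 76.8 ± 1.76 to 31.4 ± 4.10 CPM (-1.29, SE 0.110, adjusted p = 1.664e-05). The interferon-induced non-coding RNA AW112010 fell from 148 ± 8.63 to 58.1 ± 5.64 CPM (-1.35, adjusted p = 2.404e-06). Ly6a, an interferon-inducible surface protein, fell from 483 ± 51.3 to 207 ± 36.3 CPM (-1.22, adjusted p = 2.849e-05). Cd74, the chaperone of MHC class II, fell from 34.2 ± 8.12 to 11.5 ± 0.745 CPM (-1.57, adjusted p = 0.0001893). Transcripts of other cell types at like levels fell in these colonocytes too, among them the light chain gene Iglc3 (-2.30) and the matrix gene Dcn (-1.33, a call lost with DESeq2, with doublets kept and without control library 2, at -0.98). Zbp1, a sensor of viral nucleic acid, fell by 1.53 on the log2 scale (adjusted p = 4.687e-05). Undivided epithelial cells gave -1.70 for Psmb8 (99.4 ± 9.91 to 30.6 ± 1.08 CPM, adjusted p = 5.872e-08), -1.30 for Ly6a (adjusted p = 3.915e-06) and -1.30 for AW112010 (adjusted p = 1.295e-05). In goblet cells Psmb8 fell from 28.9 ± 0.730 to 10.7 ± 0.605 CPM (-1.43, adjusted p = 0.002865). None of the named colonocyte genes was past the threshold without the low-count filter, where Psmb8 came closest (adjusted p = 0.05056). With stricter cells (at least 500 genes and at most 10% mitochondrial counts) Cd74 (-1.16) and Zbp1 (-1.50) also missed it in colonocytes. The median mitochondrial share of colonocytes was 15.5% and 15.3% in the control and 16.3% and 14.9% in the CCl4 libraries. The stricter limit thus removed most of them.

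The list of MHC class I presentation genes was lower in all 8 classes at the preset correlation of 0.01 and in none with an estimated correlation (lowest adjusted p = 0.277), as camera from limma tested it against the other genes. In colonocytes its 16 members had a median log2 ratio of -0.42 (adjusted p = 1.415e-16), with 0 higher and 6 lower over all genes and 0 and 12 adjusted over the list alone. In undivided epithelial cells the median was -0.31 (adjusted p = 1.744e-12; 0 higher and 5 lower over all genes, 0 and 9 adjusted over the list alone), and in goblet cells it was -0.20 over 15 members (adjusted p = 0.0029; 0 and 2 over all genes, 0 and 3 adjusted over the list alone). The interferon response list had medians of -0.63 in colonocytes (26 members, adjusted p = 1.275e-13; 0 higher and 5 lower over all genes, 0 and 11 adjusted over the list alone), -0.39 in undivided epithelial cells (16 members, adjusted p = 2.652e-06; 0 and 4, and again 0 and 4 adjusted over the list alone) and -0.22 in goblet cells (19 members, adjusted p = 0.009319; 0 and 1, and 0 and 5 adjusted over the list alone). MHC class II genes were lower in colonocytes (10 members, median -0.91, adjusted p = 5.261e-06; 0 and 4, and 0 and 5 adjusted over the list alone). None of these calls held with an estimated correlation either: the colonocyte lists had an adjusted p = 0.277 each. With 4 libraries, few residual degrees of freedom remain to estimate a correlation, so a list could hardly pass there. The goblet calls of both lists were lost without CCl4 library 1 (-0.07 for MHC class I, -0.03 for interferon), and the goblet interferon call without control library 2 (-0.12). The colonocyte MHC class II call was lost with stricter cells (0.10), and the immunoglobulin list was lower in colonocytes beside it (-0.54, adjusted p = 0.001007, and 0.390 with an estimated correlation).

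**Figure D2:**
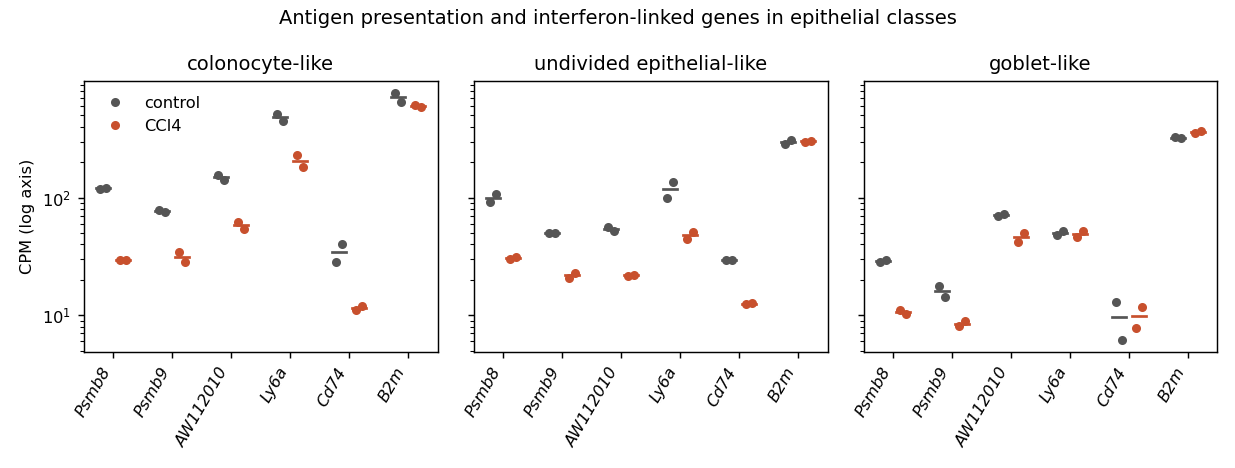
Levels of antigen presentation and interferon-linked genes in the 3 epithelial classes, in CPM on a log axis. Cd74, the chaperone of MHC class II, is among them. Bars give the mean of 2 libraries and dots the libraries. Psmb8 in colonocytes lay at 120 CPM in control and 29.7 CPM in CCl4 libraries.

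Other colonocyte transcripts went both ways. Cyp2c68, a cytochrome P450 of the family that oxidises drugs and fatty acids, rose from 46.2 ± 0.0839 to 97.8 ± 2.77 CPM (log2 ratio 1.08, SE 0.0953, edgeR adjusted p = 2.006e-05). Its near copy Cyp2c69 rose by 0.71 (adjusted p = 0.001436), a call lost with stricter cells (0.84). Sycn, which encodes a secretory granule protein, rose in colonocytes (0.75, adjusted p = 0.0003778) and in undivided epithelial cells from 702 ± 25.7 to 1384 ± 17.5 CPM (0.98, SE 0.0721, adjusted p = 5.872e-08). Gasdermin C genes, whose products form pores in membranes, were lower in colonocytes (Gsdmc2 -0.73, Gsdmc4 -0.62) and Gsdmc2 in undivided epithelial cells (-0.76, adjusted p = 1.339e-05). Both colonocyte gasdermin calls were lost without control library 2 (-0.83 for Gsdmc2, -0.65 for Gsdmc4). Reg3b, an antimicrobial lectin, rose in colonocytes from 240 ± 36.2 to 405 ± 115 CPM (0.76, adjusted p = 0.01772) and fell in undivided epithelial cells from 193 ± 104 to 80.6 ± 32.7 CPM (-1.28, adjusted p = 0.004441). Both Reg3b calls were lost with DESeq2, the undivided epithelial one with doublets kept (-0.72), at resolution 2.0 (-0.86) and with the first doublet rule (-0.54), and the colonocyte one also without control library 2 (0.60) or CCl4 library 2 (0.43). Family members such as Gsdmc2 and Gsdmc4, Cyp2c68 and Cyp2c69 or Hba-a1 and Hba-a2 have near-identical sequences, so the split of counts between them is uncertain.

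In undivided epithelial cells, Ttr, a carrier of thyroid hormone, rose from 20.03 ± 2.40 to 64.6 ± 1.89 CPM (log2 ratio 1.69, SE 0.150, edgeR adjusted p = 7.688e-07). Apol10a, an apolipoprotein L gene, fell (-1.26, adjusted p = 1.667e-06). The proliferation genes Top2a (-0.58, adjusted p = 0.005556) and Ube2c (-0.61, adjusted p = 0.00428) were lower, but neither was past the threshold with stricter cells, with doublets kept or without CCl4 library 1 (-0.52 for Top2a, -0.54 for Ube2c). The cell cycle list of 26 members was lower there (median -0.29, adjusted p = 0.0001605, and 0.286 with an estimated correlation; 0 higher and 2 lower over all genes, 0 and 2 adjusted over the list alone), a call lost with doublets kept (-0.04) and with stricter cells (-0.19). The tight junction gene Cldn4 rose by 0.99 (89.8 to 178 CPM), a call lost with DESeq2 (0.98), with doublets kept (0.19) and with stricter cells (0.72). A cluster of 89 cells led by Cldn4 lay in this class. It held 9 of 469 and 4 of 410 control cells, and 46 of 1258 and 30 of 1077 CCl4 cells. Its median was 18045 counts per cell, against 5697 in the other cluster of the class. Cldn4 was not tested without it, so the mix of cells is not told apart from a change within cells. The list of nuclear oxidative phosphorylation genes was lower (30 members, median -0.10, adjusted p = 7.494e-05, and 0.390 with an estimated correlation; 0 and 5 over all genes, 3 and 10 adjusted over the list alone). For the list of epithelial transcripts that can leak, signs differed in this class: the median was -0.20, the mean was 0.03, and the test called it lower (adjusted p = 0.0004586, and 0.289 with an estimated correlation; 1 and 5 over all genes, 4 and 9 adjusted over the list alone).

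Goblet cells of CCl4 mice held less message of 2 of their main products, relative to all their counts. Retnlb, an antibacterial protein secreted by goblet cells, fell from 2462 ± 475 to 1274 ± 52.2 CPM (log2 ratio -0.95, SE 0.104, edgeR adjusted p = 0.00104). Muc2, the gel-forming mucin of the colon, fell from 7874 to 5535 CPM (-0.51, adjusted p = 0.01336). Sval1, a member of the seminal vesicle antigen family, rose from 101 ± 44.8 to 506 ± 61.2 CPM (2.32, SE 0.207, adjusted p = 0.00025). The sulfotransferase Sult1a1 rose from 12.3 to 58.8 CPM (2.28, adjusted p = 0.001056) and the water channel Aqp4 from 5.47 to 22.2 CPM (2.01). Nlrp6, an inflammasome sensor, rose from 4.90 to 14.8 CPM (1.59). These low levels moved beside transcripts of other cell types, since goblet cells also gained Hbb-bs (5.15, call lost with stricter cells at 4.92) and the collagen gene Col3a1 (1.21, call lost with doublets kept at 0.09 and with the first doublet rule at 0.08). Sult1a1 and Aqp4 also rose in fibroblasts (1.14, call lost with stricter cells at 0.99, and 2.17). The xenobiotic list was higher in fibroblasts as well (24 members, median 0.51, adjusted p = 7.912e-05, and 0.277 with an estimated correlation; 3 higher and 0 lower over all genes, 5 and 0 adjusted over the list alone). The endoplasmic reticulum stress gene Chac1 fell by 0.98 on the log2 scale. The xenobiotic metabolism list was higher (26 members, median 0.67, adjusted p = 9.666e-06, and 0.277 with an estimated correlation; 2 higher and 0 lower over all genes, 8 and 1 adjusted over the list alone). The mitochondrially encoded list was also higher (13 members, median 0.44, adjusted p = 5.723e-23, and 0.277 with an estimated correlation; 9 and 0 over all genes, 12 and 0 adjusted over the list alone), beside the higher mitochondrial share of these libraries.

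Fibroblasts, the class with the most cells, held less message for factors that help proteins fold in the endoplasmic reticulum. Creld2 fell from 151 ± 11.1 to 70.8 ± 8.36 CPM (log2 ratio -1.09, SE 0.101, edgeR adjusted p = 1.254e-05), and Manf, a secreted stress factor, from 287 ± 8.12 to 145 ± 5.02 CPM (-0.98, SE 0.0824, adjusted p = 3.969e-06). Creld2 lies on chromosome 15 at 88819646 to 88826683 and Manf on chromosome 9 at 106838312 to 106891979 of GRCm38. Ackr4, a receptor that removes chemokines, fell from 492 ± 10.1 to 292 ± 62.4 CPM (-0.75, adjusted p = 0.001729). The unfolded protein response list was lower (20 members, median -0.34, adjusted p = 1.887e-13, and 0.286 with an estimated correlation; 0 higher and 9 lower over all genes, 1 and 11 adjusted over the list alone). The clock output gene Dbp rose from 16.9 ± 0.366 to 39.5 ± 1.23 CPM (1.22, SE 0.130, adjusted p = 6.147e-05). The circadian list was higher with it (16 members, median 0.27, adjusted p = 5.732e-05, and 0.390 with an estimated correlation; 4 and 0 over all genes, 5 and 1 adjusted over the list alone). In these fibroblasts the calls of Creld2, Manf, Ackr4 and Dbp held under each alternative that was run.

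Inflammatory and growth factor response genes of fibroblasts were modestly higher. Il6 rose from 59.0 ± 9.44 to 89.3 ± 2.29 CPM (log2 ratio 0.60, edgeR adjusted p = 0.01054) and the chemokine Cxcl10 from 110 ± 3.47 to 169 ± 16.4 CPM (0.62, adjusted p = 0.001729). Socs3, a feedback inhibitor of cytokine signals, rose by 0.49 (adjusted p = 0.005659) and Id1, a target of bone morphogenetic protein signals, by 0.67 (adjusted p = 0.005908). Socs3 was also on the list of immediate early and dissociation response genes. Tissue dissociation as a source of these changes was not tested. Cxcl10 fell in colonocytes (-0.82, adjusted p = 0.02122), a call lost with DESeq2, with stricter cells, at resolution 2.0 and without control library 1 (-0.42). The NF-kB list was higher in fibroblasts (18 members, median 0.13, adjusted p = 0.01365, and 0.322 with an estimated correlation; 3 and 0 over all genes, 4 and 0 adjusted over the list alone). The TGF-beta response list was also higher (20 members, median 0.10, adjusted p = 0.003899, and 0.302 with an estimated correlation; 3 and 0, and 5 and 0 adjusted over the list alone), a call lost with doublets kept (0.07). Matrix genes moved little: the extracellular matrix list had a median of 0.11 in fibroblasts (28 members, adjusted p = 0.007267, and 0.489 with an estimated correlation; 3 and 1, and 7 and 3 adjusted over the list alone). That call was lost without control library 2 (0.11), without CCl4 library 1 (0.06) and with doublets kept (0.06). Postn, a matrix protein of wound repair, rose by 0.39 (adjusted p = 0.01103) and Sparc by 0.32 (adjusted p = 0.02362), and both calls were lost without CCl4 library 1 (0.38 and 0.32) or 2 (0.40 and 0.33). The mix of fibroblast clusters differed between groups. A cluster with Postn among its leading genes held 694 and 751 control and 793 and 761 CCl4 cells. One with Ackr4 among them held 1012 and 984 control and 790 and 633 CCl4 cells. For these 2 genes, the mix was not tested apart from a change within cells.

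T cells of CCl4 mice held less effector message. Gzma, a protease of cytotoxic granules, fell from 1129 ± 343 to 381 ± 48.0 CPM (log2 ratio -1.56, SE 0.175, edgeR adjusted p = 0.0005335). Interferon gamma, Ifng, fell from 1220 ± 282 to 505 ± 28.0 CPM (-1.27, SE 0.147, adjusted p = 0.0006685). Il17a, a cytokine of mucosal defence, fell from 62.2 ± 16.3 to 19.7 ± 0.473 CPM (-1.65, adjusted p = 0.004375), a call lost with doublets kept (-0.86). The chemokine gene Ccl4, unrelated to the toxin, fell from 121 to 43.0 CPM (-1.50, adjusted p = 0.003194). The effector list was lower (23 members, median -0.33, adjusted p = 4.606e-07, and 0.277 with an estimated correlation; 0 higher and 4 lower over all genes, 1 and 9 adjusted over the list alone). The heat shock genes Hspa1a (-0.72) and Dnajb1 (-0.71) were lower, and so was their list (13 members, median -0.27, adjusted p = 6.379e-12, and 0.297 with an estimated correlation; 0 and 2, and 0 and 5 adjusted over the list alone). Hspa1a was not past the threshold without CCl4 library 2 (-0.64).

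Macrophages and monocytes differed in a few immune genes. The mix of clusters in this class also differed between groups. A cluster with Mrc1 among its leading genes held 442 and 406 control and 395 and 336 CCl4 cells. One with Il1b among them held 212 and 206 control and 259 and 257 CCl4 cells. For the genes below, the mix was not tested apart from a change within cells. Ifnb1, a type I interferon, rose from 11.6 ± 2.35 to 52.3 ± 16.7 CPM (log2 ratio 2.17, SE 0.281, edgeR adjusted p = 0.0002667), and the placental growth factor Pgf from 30.5 to 103 CPM (1.76, adjusted p = 4.969e-05). The interferon-induced GTPase Iigp1 fell from 34.5 to 6.28 CPM (-2.46, adjusted p = 0.0002106). Slc15a2, a carrier of di- and tripeptides, fell from 61.0 ± 0.631 to 11.7 ± 2.97 CPM (-2.39, SE 0.243, adjusted p = 3.509e-05). Retnla, a marker of alternatively activated macrophages, fell by 1.16 on the log2 scale (adjusted p = 0.001272), a call lost with DESeq2. The interferon response list was lower (25 members, median -0.25, adjusted p = 0.0003349, and 0.286 with an estimated correlation; 2 higher and 4 lower over all genes, 2 and 4 adjusted over the list alone), but not past the threshold without CCl4 library 1 (-0.17).

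In endothelial cells the vessel transcription factor Sox18 fell from 435 ± 12.8 to 253 ± 14.0 CPM (log2 ratio -0.78, SE 0.102, edgeR adjusted p = 0.0002425). Psmb9 fell there by 0.71 on the log2 scale (adjusted p = 0.002457), and the heat shock gene Hspa8 rose by 0.47 (adjusted p = 0.008199). The endothelial barrier list was not past the threshold in any of the 8 classes. In smooth muscle the cardiac-type actin Actc1 fell from 168 ± 37.5 to 83.7 ± 17.2 CPM (-0.999, SE 0.163, adjusted p = 8.698e-05). C1qtnf3 (18.4 to 131 CPM, 2.82), Igfbp3 (45.2 to 293 CPM, 2.70) and the matrix gene Dcn (445 to 1114 CPM, 1.32) were higher in smooth muscle. So was the list of extracellular matrix in smooth muscle (27 members, median 0.68, adjusted p = 7.029e-34, and 0.277 with an estimated correlation; 15 higher and 1 lower over all genes, 22 and 1 adjusted over the list alone). The class held a cluster of 71 cells with fibroblast markers, 5 and 2 in the control and 36 and 28 in the CCl4 libraries. Without it 72 genes were called in place of 260, C1qtnf3 (1.42), Igfbp3 (0.11) and Dcn (0.13) were not past the threshold, and the list median was 0.16 (adjusted p = 0.08006).

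Transcripts that belong to other cell types moved in the 5 non-epithelial classes, beside the changes given for them above. Muc2 rose in fibroblasts from 40.8 ± 6.95 to 126 ± 0.292 CPM (log2 ratio 1.63, SE 0.111, edgeR adjusted p = 6.482e-07) and in T cells from 53.6 to 157 CPM (1.56, adjusted p = 0.0003204). Epcam, an epithelial adhesion protein, rose in macrophages from 22.7 to 66.0 CPM (1.54). Igha, the heavy chain of secretory antibody, fell in fibroblasts from 689 ± 20.8 to 226 ± 21.7 CPM (-1.61, SE 0.0865, adjusted p = 3.41e-08), in T cells (-1.86), in endothelial cells (-1.57) and in smooth muscle (-1.34, reversed to 0.20 with the first doublet rule). In macrophages Igha went the other way, not past the threshold (1.01, adjusted p = 0.475), with 2755 CPM in CCl4 library 2 and 301 CPM in CCl4 library 1. The beta globin gene Hbb-bs rose in endothelial cells from 25.8 to 209 CPM (3.02) and Hba-a2 in fibroblasts from 8.72 ± 0.489 to 131 ± 26.4 CPM (3.91, adjusted p = 1.598e-09), the latter not past the threshold with doublets kept (1.24). The list of epithelial transcripts that can leak took 0.0528% and 0.0476% of fibroblast counts in the control and 0.112% and 0.124% in the CCl4 libraries. It was higher in fibroblasts (18 members, median 1.24, adjusted p = 6.289e-37, and 0.277 with an estimated correlation; 11 and 0 over all genes, 17 and 0 adjusted over the list alone), T cells (1.19), endothelial cells (0.97), macrophages (1.02) and smooth muscle (0.95). These calls of the epithelial leak list were made at the preset correlation, and none held with an estimated one (lowest camera adjusted p = 0.277). The immunoglobulin list was lower in fibroblasts (-1.18, adjusted p = 2.43e-16), T cells (-1.19, adjusted p = 9.77e-08) and endothelial cells (-1.09, adjusted p = 6.841e-12), none of them with an estimated correlation (adjusted p = 0.277, 0.286 and 0.277), and it was not past the threshold in macrophages (adjusted p = 0.3931). The T cell call was not past the threshold with free RNA subtracted (-0.40).

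**Figure D3:**
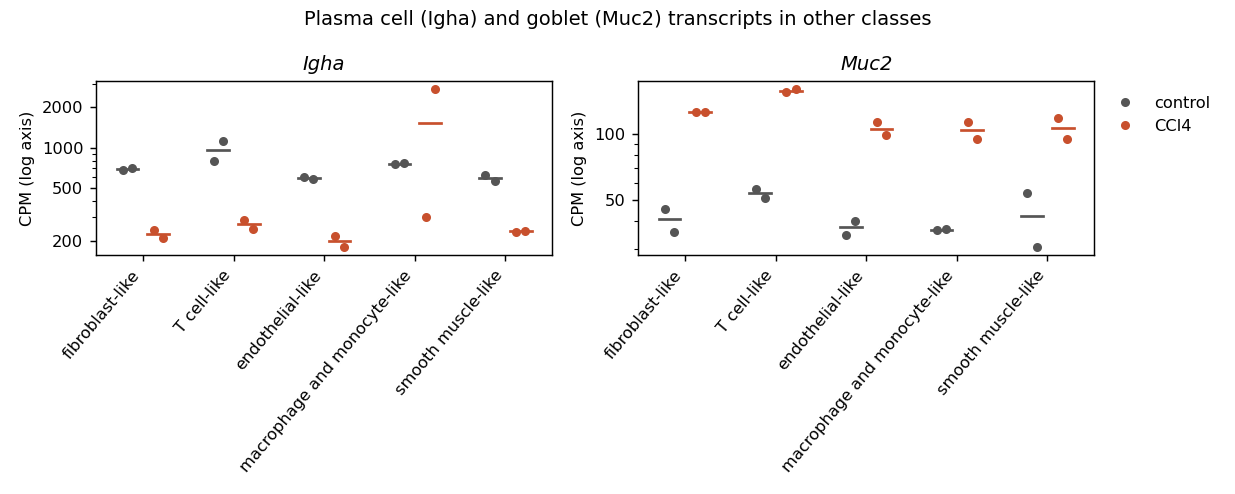
Levels of transcripts such as Muc2 and Igha in classes that are not their main source, in CPM on a log axis, with bars for the mean of 2 libraries and dots for the libraries. Muc2 in fibroblasts lay at 40.8 CPM in control and 126 CPM in CCl4 libraries, and Igha at 689 and 226 CPM.

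Of 252 pairs of a list and a class, 123 were past the threshold with the preset correlation, 72 higher and 51 lower in CCl4. With an estimated correlation 0 were past it (lowest adjusted p = 0.277), and the rotation test fry also called 0. With 4 libraries, few residual degrees of freedom remain for these tests, so their 0 calls say little either way. Across the 8 classes, MHC class I genes were lower in 8, interferon response genes in 7, MHC class II genes in 4 and unfolded protein response genes in 3. Some lists share members, so their calls are not independent. Psmb8 and Psmb9 were on both the MHC class I and the interferon lists. Zg16 was on the mucus, antimicrobial and epithelial leak lists. The fibroblast interferon response call (median -0.16, adjusted p = 0.04419) was lost without control library 1 (-0.17) or 2 (-0.11) and without CCl4 library 1 (-0.16) or 2 (-0.14). The smooth muscle MHC class I call (-0.15, adjusted p = 0.009994) was lost without control library 1 (-0.04). Mitochondrially encoded genes were higher in 7 classes, mucus genes in 7, ion and water transport genes in 6 and antimicrobial genes in 5. In the non-epithelial classes the higher mucus, transport, junction and antimicrobial lists were measured beside the higher epithelial leak list. Cytosolic ribosomal genes were higher in 5 classes, xenobiotic genes in 4, stem and Wnt genes in 2, and apoptosis, cholesterol synthesis and glycolysis genes in 1 each. Junction genes were higher in 4 classes and lower in 1, and immediate early and dissociation response genes in 3 and 1. Pyroptosis genes were higher in 3 and lower in 2, chemokines in 2 and 1, and bile acid genes in 2 and 1. NF-kB and heat shock genes were each higher in 3 classes and lower in 2, extracellular matrix genes in 3 and 1, and cell cycle genes in 1 and 1. Lymphocyte effector genes were higher in 1 and lower in 1 of 5 classes tested, and TGF-beta and circadian genes were each higher in 1 of 8. Nuclear oxidative phosphorylation genes were lower in 2 classes, the plasma and myeloid leak list in 6 and the immunoglobulin list in 7. The epithelial leak list was higher in 6 and lower in 1. Fatty acid oxidation genes were past the threshold in 0 of the 8. The haemoglobin list never had 5 members past the low-count filter and was not tested.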

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

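Several of the tests here were chosen only after the result was seen. These were the comparison with a free RNA profile (as narrowed and divided by transcript type) and the comparison of levels between classes. The droplet test of immunoglobulin transcripts, the comparison of variable segments and the scaled subtraction were chosen after it as well. The others were chosen before, except that the unscaled subtraction of free RNA used a setting added after the data were seen. The differences between classes below were tested with an interaction term in edgeR for named genes called in opposite directions in a pair of classes, so the genes were picked for the difference that was tested. The cluster and barcode shares concern cells outside the named classes and were compared with the control libraries without a test.

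Muc2 fell in goblet cells while it rose in colonocytes (difference of log2 ratios -1.86, adjusted p = 2.512e-05) and in undivided epithelial cells (-2.03, adjusted p = 1.038e-08). The rise of Muc2 in undivided epithelial cells was a call lost with doublets kept (1.15) and with stricter cells (1.09). The same gap to goblet cells was measured for classes that are not epithelial, such as fibroblasts (-2.15) and T cells (-2.05), so it is not a difference among epithelial classes alone. Gsdmc4 fell in colonocytes, a call lost without control library 2, and rose in goblet cells, a call lost with stricter cells (difference 1.83, adjusted p = 0.0002526). Hid1, which acts in protein sorting, rose in undivided epithelial cells and fell in goblet cells (-1.38, adjusted p = 3.444e-05), and the former call was lost with doublets kept (0.74) and with stricter cells (1.19). Reg3b rose in colonocytes and fell in undivided epithelial cells (2.01, adjusted p = 0.002524), and both calls behind it were lost with DESeq2. Among clusters without a name, cluster 2 took 9.78% of CCl4 cells against 6.80% of control cells, and had the higher mitochondrial medians of 15.7% in both CCl4 libraries against 13.7% and 13.6%. Cluster 21 took 1.66% against 0.391% and cluster 17 took 1.95% against 1.71%. Cluster 21 scored 3.13 for endothelial and 2.91 for pericyte markers. Its median was 10587 counts per cell, against 3531 in the largest endothelial cluster. For cluster 21, cells caught together in a droplet were not told apart from a cell type. Cluster 14 was larger in both libraries numbered 2, with 0.0867% and 3.04% of control and 0.993% and 5.47% of CCl4 cells, so the groups overlapped. Barcodes above the mitochondrial limit, left out of every comparison, made up 18.5% of CCl4 barcodes as the mean of 20.9% and 16.2%, with 13.7% and 12.4% in the control libraries.

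Epithelial transcripts were higher in the 5 non-epithelial classes of CCl4 mice, and immunoglobulin transcripts were lower in 4 of them, with Igha higher but not past the threshold in macrophages (1.01). Free RNA with the make-up of the retained cells, first written for free RNA of any make-up, was excluded for the epithelial transcripts alone. With its amount read from Igha, they stood at a median of 4.83 times the predicted level (4.41, 3.85, 5.70 and 5.30 per library). Immunoglobulin genes other than Igha stood at 0.862 and could come from it. They share their main source with Igha, so any other source of plasma cell transcripts would give a like ratio. Without the 5% of cells richest in epithelial transcripts, at least 0.992 of their log2 ratio between groups was kept in each class. Without the 5% richest in immunoglobulin transcripts, at least 0.862 was kept in the 4 classes. The Igha level in macrophages was not tested this way. A few cells caught together in a droplet thus did not carry these changes, but multiplets as a whole were not excluded. In smooth muscle, Lgals4 (1.12) and Krt8 (0.96) lost their calls with doublets kept and with the first doublet rule. Igha moved to 0.20 there with the first doublet rule. Muc2 in smooth muscle, and Lgals4 and Krt8 in endothelial cells, held under each alternative. Free RNA richer in epithelial transcripts than the retained cells remains a candidate source, since a single source gives all classes a like level. The highest level among the 5 classes was at most 1.74 times the lowest (median over genes, with 1.64, 1.71, 1.51 and 1.74 per library). Single genes lay above these medians, most of all Car4, which was highest in endothelial cells (42.9 in control library 1). Others were Krt18 (2.64 in control library 1), Car1 (2.65 in CCl4 library 2) and Slc26a3 (2.48 in CCl4 library 2).

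MHC class I and interferon genes were lower in the 3 epithelial classes, as lists at the preset correlation only (lowest adjusted p = 0.277 with an estimated one). Subtracting free RNA left 0.950 of the median change (95% interval 0.914 to 1.13) and stricter cells left 1.04 (0.663 to 1.47). Clusters taken one by one at resolution 2.0 left 0.986 (0.841 to 1.17, 7 clusters with medians from -0.629 to -0.12). The median change thus remained where free RNA from lysed cells, damaged cells or another mix of cells was reduced in these ways. The intervals resampled genes and not libraries. They leave out the spread between libraries, so none of the 3 sources was excluded. The subtraction removed too little epithelial RNA, and a version scaled up to the epithelial level left 1.76 (1.37 to 2.16). Lower interferon signalling in the epithelium stays open as an untested hypothesis, since T cells held less of the ligand Ifng (-1.27) but macrophages held more of the ligand Ifnb1 (2.17), and the interferon target Cxcl10 was higher in fibroblasts (0.62). Housing or other differences between animals were not tested.

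The libraries within a group used like immunoglobulin variable segments in plasma cells, and the groups used different ones. Ighv2-4 led in 78 and 53 control and 0 and 0 CCl4 plasma cells, of 490, 500, 269 and 232 with a clear segment. The distance between the control libraries was 0.202 and was reached in 0.122 of random splits of their pooled cells, and that between the CCl4 libraries was 0.298 and was reached in 0.077 of splits. Between groups, distances were 0.481 to 0.554, reached in 0 of 2000 splits. The same animals in both libraries of a group could give this, in which case n = 2 counts technical repeats and each p-value of the comparisons describes a single pool per group. Inbred animals that share housing were not tested as another source.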

How the results depend on the processing

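The first doublet rule, the first naming rule, the clustering without called genes, smooth muscle without the mixed cluster, free RNA subtracted and every fit of the 4 added classes (plasma cells, glia, natural killer and innate lymphoid cells, lymphatic endothelial cells) were chosen only after the result was seen, and the other tests before. The 13 counts and 557 named genes below include these 4 classes, and the sum of called genes does not. The cause of a change was not tested except where stated. Relative log expression factors moved none of the 13 counts of genes by over 1.5 times, and kept 546 of 557 named genes and 123 of 123 list pairs on their side of the threshold. Of the same 557, DESeq2 kept 472, resolution 2.0 532 and no low-count filter 449. Fewer could be compared with free RNA subtracted (501 of 526 kept), with doublets kept (408 of 556) and with stricter cells (423 of 543).

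The sum of 1436 called genes over 8 classes was 773 with stricter cells, 1055 with DESeq2, 1413 with relative log expression factors, 2138 without the low-count filter, 1420 with doublets kept, 1221 at resolution 2.0, 1184 with the first doublet rule and 1276 with free RNA subtracted. Fibroblasts gave 469 without the filter, 489 with doublets kept and 141 with stricter cells. Undivided epithelial cells gave 246 with DESeq2, 31 with doublets kept, 48 with stricter cells, 193 at resolution 2.0 and 242 with the first doublet rule. Colonocytes gave 0 in edgeR without the filter (1610 at an unadjusted p under 0.05, DESeq2 122 with the filter), 73 with doublets kept, 62 with stricter cells and 98 at resolution 2.0. T cells gave 116 without the filter, 187 with doublets kept and 79 with the first doublet rule. Endothelial cells gave 164, 270 and 43 under the same settings. Goblet cells gave 403 without the filter and 70 with stricter cells. Smooth muscle gave 114 with DESeq2, 111 with doublets kept, 123 with the first doublet rule and 72 without the mixed cluster, where the 71 removed cells carried fibroblast markers. Stricter cells leave fewer cells and counts (5815, 5956, 6163 and 6074 cells).

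With each library left out in turn, the sum ranged from 1004 (without CCl4 library 2) to 3016 (without control library 1), with 2447 without control library 2. Fibroblasts ranged from 187 (CCl4 2 out) to 491 (control 1 out), undivided epithelial cells from 167 (CCl4 2 out) to 836 (control 1 out) and colonocytes from 28 (control 2 out) to 186 (control 1 out). T cells ranged from 64 (CCl4 2 out) to 117 (control 2 out), endothelial cells from 63 (CCl4 1 out) to 262 (control 1 out) and macrophages from 113 (CCl4 2 out) to 244 (control 2 out). Goblet cells ranged from 121 (CCl4 2 out) to 605 (control 1 out) and smooth muscle from 146 (CCl4 2 out) to 318 (control 1 out). Other counts moved by over 1.5 times were 481 in fibroblasts, 589 in undivided epithelial cells, 222 in endothelial cells and 503 in goblet cells with control 2 out, 92 in T cells and 226 in macrophages with control 1 out, and 190 in undivided epithelial cells, 105 in T cells and 210 in goblet cells with CCl4 1 out.

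For shares, TMM factors brought enteroendocrine cells (0.58), glia (0.29) and lymphatic endothelial cells (0.39) past the threshold. Within epithelial or non-epithelial totals the sign of colonocytes (-0.55), natural killer and innate lymphoid cells (0.27), endothelial cells (0.19), macrophages (0.10) and smooth muscle (0.0522) reversed, fibroblasts lost their call (-0.065), and glia (0.63) and lymphatic endothelial cells (0.73) passed. This follows from the changed total. Stricter cells ended the calls of colonocytes (0.0216), endothelial cells (-0.013) and macrophages (-0.11), and brought enteroendocrine cells (0.76) and glia (0.37) past the threshold. That limit removed most colonocytes and undivided epithelial cells, so these shares describe another set of cells. The share of colonocytes also lost its call with doublets kept (0.0453), at resolution 2.0 (0.10), with the first doublet rule (0.16) and without called genes (0.17). Endothelial cells lost theirs with doublets kept (-0.20), and interstitial cells of Cajal reversed with the first doublet rule (-0.89). The first naming rule changed no share call among the 15 classes it named. Undivided epithelial and erythroid cells had no value in the clustering without called genes, nor erythroid cells without CCl4 library 1.

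With each library left out, the number of share calls ranged from 5 (without CCl4 library 1, or 2) to 12 (without control library 1). The lowest and highest values were 1.21 and 2.07 for B cells (call lost without either CCl4 library), 0.17 and 0.37 for colonocytes (lost without control 2, CCl4 1 or CCl4 2) and -0.28 and -0.21 for endothelial cells (lost without control 1, CCl4 1 or CCl4 2). They were 0.35 and 0.66 for enteroendocrine cells and 0.0338 and 0.39 for glia (both past the threshold without control 1), 3.71 and 7.09 for erythroid cells (lost without CCl4 2), -0.39 and -0.27 for macrophages (lost without either CCl4 library), -0.43 and -0.33 for smooth muscle (lost without CCl4 2) and 0.99 and 1.22 for undivided epithelial cells (lost without CCl4 1). Calls of goblet, plasma and T cells and fibroblasts held in each of these.

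Of the 123 list pairs, 0 were past the threshold with an estimated correlation and 0 with fry. With 4 libraries, few residual degrees of freedom remain for either test, so a list could hardly pass. These 0 calls do not show that the lists were unchanged, and the calls at the preset correlation stay without backing from either test. Leaving out a library kept between 99 and 112 pairs on their side. The extracellular matrix list in goblet cells reversed with the first doublet rule (-0.38). The plasma cell and myeloid leak list in colonocytes ranged from -1.48 (without CCl4 1) to 0.46 (without CCl4 2), where it reversed. Among named genes past the threshold in at least 1 of the fits compared, Il31ra in undivided epithelial cells (0.37), Adamdec1 in lymphatic endothelial cells (-0.61) and Dmbt1 in smooth muscle (-0.22) reversed with doublets kept. Adamdec1 (-0.17) and, in smooth muscle, Igha (0.20), Jchain (0.34) and Igkc (0.50) reversed with the first doublet rule, and Clec3b in smooth muscle without the mixed cluster (-0.0253). The sign also changed for 8 named genes past the threshold in neither fit. These were Igha in colonocytes (1.65 with stricter cells, 0.0158 without CCl4 2), Igha in natural killer and innate lymphoid cells (1.998 with free RNA subtracted), Bgn (-0.46) and Sparc (-0.38) in goblet cells and Cavin1 in plasma cells (-0.24), each with the first doublet rule and with doublets kept (-0.0487, -0.0553 and -0.35), Cxcl2 in glia (0.12 without control 1), and Tff3 (-0.25) and Fos (-0.0653) in lymphatic endothelial cells with doublets kept.

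The replicate block took the library number as a shared factor in 2 pairs, although no label says what the number marks. Correlations within pairs lay between -0.02 and 0.17. With the replicate block the sum was 2343, with 710 in fibroblasts, 154 in T cells, 159 in endothelial cells, 232 in macrophages, 349 in goblet cells and 125 in smooth muscle, and 0 share calls changed. The block takes up a degree of freedom, so a call lost under it does not by itself show a weaker effect. Why counts rose in some classes and fell in smooth muscle was not tested.

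Fewer changes could be seen in the added classes: of 100 genes changed 2-fold in simulation, 23 were recovered in plasma cells, 34 in glia, 24 in natural killer and innate lymphoid cells and 15 in lymphatic endothelial cells, against 76 in colonocytes. The smallest sums of the last 3 were 732543, 414241 and 263810 counts. Plasma cells had larger sums than smooth muscle (at least 3380236 against 1647577 counts, with 47 recovered in smooth muscle) and a larger coefficient of variation (0.166 against 0.119), and depth was not tested apart from spread.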

Other observations

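The 4 classes below and the comparison of a gene over several classes were chosen only after the result was seen, and none of the tests here was planned.

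Plasma cells of CCl4 mice held less message for the heavy chains of IgG2, an antibody class of systemic responses. Ighg2c stood at 2012 and 916 CPM in the control and 0.671 and 0.280 CPM in the CCl4 libraries (edgeR adjusted p = 9.136e-06). Ighg2b fell from 1536 ± 147 to 170 ± 69.9 CPM (mean ± SD, n = 2; log2 ratio -3.17, edgeR adjusted p = 0.0002195). Ighg2c and Ighg2b have similar sequences, so the split of counts between them is uncertain. Plasma cells of the 2 groups also used different variable segments, as given above. Other clones or animals in a group thus cannot be told apart from an effect of the treatment on IgG2 message. The cell cycle list was lower in plasma cells (26 members, median -0.89, adjusted p = 1.722e-14, and 0.312 with an estimated correlation; 0 higher and 4 lower over all genes, 0 and 21 adjusted over the list alone). In all 161 genes were called, 113 of them higher, and 39 of the 161 were antibody variable segments (of 143 tested), which follow the clones present. Leaving out control library 1 or 2 lowered the 161 to 40 and 22. The epithelial leak list was higher in plasma cells too (17 members, median 1.55, adjusted p = 2.065e-25, and 0.312 with an estimated correlation; 11 and 0 over all genes, 17 and 0 adjusted over the list alone).

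Glia called 58 genes, natural killer and innate lymphoid cells 8 and lymphatic endothelial cells 7. In glia the interferon-induced GTPase Ifi47 fell from 62.2 to 11.96 CPM (log2 ratio -2.38, edgeR adjusted p = 0.00221), a call that held under each alternative that was run. In natural killer and innate lymphoid cells the chaperone genes Dnajb1 (2208 to 1131 CPM, -0.96) and Hspe1 (-0.74) were lower, and neither was past the threshold without CCl4 library 2 (-0.92 and -0.65) or with stricter cells (-0.90 and -0.74), nor Hspe1 without control library 1 (-0.66). In lymphatic endothelial cells the collagen genes Col1a2 (12.2 to 308 CPM) and Col3a1 (36.2 to 411 CPM) were higher, and Col1a2 was not past the threshold with doublets kept (1.32) or with the first doublet rule (2.17). Counts moved with single libraries: glia gave 113 without control library 2 and 37 without CCl4 library 2, and lymphatic endothelial cells 72 and 22 without control library 1 and 2, and 44 and 23 without CCl4 library 1 and 2. Natural killer and innate lymphoid cells gave 39 and 50 without control library 1 and 2, 15 without CCl4 library 1, and in edgeR 0 without CCl4 library 2 (281 at an unadjusted p under 0.05; DESeq2 22 on all libraries).

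Slc15a2, a peptide carrier on chromosome 16, was lower in each of the 10 classes where it could be tested and past the threshold in 7. Its log2 ratio ranged from -3.17 in endothelial cells (13.2 to 1.45 CPM) to -1.41 in colonocytes, with -2.93 in T cells (48.3 to 6.22 CPM). Psmb8 was lower in 12 of 12 classes and past the threshold in 4, and Psmb9 likewise in 12 and 4. Muc2 was higher past the threshold in 10 of 12 classes and lower in 1. The clock genes Dbp and Nr1d1 were higher past the threshold in 2 and 3 of 11 classes. The hour at which tissue was taken is not given in the labels.

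Igha stood apart in CCl4 library 2 in both macrophages (2755 CPM, against 754, 762 and 301 in control 1, control 2 and CCl4 1) and glia (2638 CPM, against 779, 633 and 333), so that its log2 ratio was 1.01 and 1.07 there, neither past the threshold (edgeR adjusted p = 0.475 and 0.4779). The Hbb-bs call in T cells rests on CCl4 library 2, with 16.8 and 5.55 CPM in the control and 36.6 and 671 CPM in the CCl4 libraries.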
